A study of Mus musculus with 6 samples.

How the data were processed

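RNA was sequenced from synovial fibroblasts sorted from inflamed ankle joints of mice as cells negative for CD45, CD31 and CD146 and positive for podoplanin (PDPN). The 6 libraries form 2 groups of 3. Ets1-flox mice carry Ets1 alleles flanked by loxP sites, and Ets1-ΔFib mice carry in addition a Col6a1-Cre transgene, which deletes the floxed sequence in cells that express it. Per the labels, the mice had the C57BL/6 background, were 8 weeks old, received 150 µL of pooled K/BxN serum on days 0, 2 and 9, and were killed on day 16. This serum carries autoantibodies that cause an arthritis (serum transfer-induced arthritis, STIA). Tissue was digested in 4 mg/mL collagenase. The number of mice, 3 per group, is given in the series design text. No paired analysis was possible because the sample numbers 1 to 6 run over both groups.

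The authors made cDNA with the SMART-seq v4 kit per the labels, sequenced it on an Ion Proton instrument per the labels and the series design text, and used CLC Genomics Workbench version 12 per the design text. The labels give mm10 as the genome build. The deposited values are read counts per Ensembl gene ID, one column per library, and were checked to be whole numbers with a different total in each library. Annotation release, aligner settings, strand and the handling of reads with several matches are not given in the sources used here. The table holds 48709 gene IDs, of which 48349 matched a symbol in GENCODE release M21 and 360 did not, and 63 symbols are shared by several IDs. Coordinates are from that annotation (GRCm38, mm10).

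Library totals were 4812047 to 6141604 counts. A count of 3, the upper limit that a count of 0 allows, corresponds to 0.488 to 0.623 CPM, counts scaled to a common library total, per library. The reads carry no molecular identifiers here, so floors and intervals cover counting error only. Since the strand is not known, counts of genes that overlap another gene are uncertain: among the 87 named genes, 17 have an exon that overlaps another gene on the opposite strand and 4 on the same strand. Near-identical copies such as Hspa1a and Hspa1b or Bglap and Bglap2 can exchange reads. Gene counts of Ets1 may include reads of exons that are not floxed, and the labels do not name the floxed exons.

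Groups, tests, thresholds, gene lists and alternatives were fixed before the data were examined, except where the text says otherwise. Genes were filtered with filterByExpr of edgeR 4.0.16, which kept 11473 genes, and scaled by the trimmed mean of M-values (TMM). Ets1-ΔFib was compared with Ets1-flox by the robust quasi-likelihood test of edgeR, with Benjamini-Hochberg adjustment over all 11473 genes and a threshold of 0.05. All log2 changes are Ets1-ΔFib minus Ets1-flox, with standard errors (SE) from the same fit, and adjusted p without another tool named are from it. CPM are TMM-scaled, with the standard deviation (SD) over 3 libraries. Two-sided exact permutation tests of 3 against 3 libraries have 20 assignments and cannot give a p below 0.1. DESeq2 1.42.0 and limma 3.58.1 (voom, with and without quality weights) were run beside edgeR, under R 4.3.3.

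The rule for named genes took Ets1 and 12 fixed genes (Tnfsf11, Tnfrsf11b, Mmp3, Mmp9, Mmp13, Mmp14, Il6, Col6a1, Pdpn, Ptprc, Pecam1, Mcam). It then took up to 12 genes per direction past the threshold with a mean of 5 CPM or more and no overlap of the groups. Where these gave fewer than 20, the genes of 5 CPM or more with the smallest unadjusted p were added up to 20, as values and not as changes. Each list added its members past the threshold or, with none, its 2 members with the smallest p. Symbols of a Gm number or ending in Rik, pseudogenes and IDs without a symbol were skipped.

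The 21 fixed gene lists cover osteoclastogenesis regulators, matrix metalloproteinases, other matrix proteases and inhibitors, inflammatory cytokines and chemokines, NF-kB targets, gp130-STAT3 signalling, interferon-stimulated genes, fibrillar collagens and collagen assembly, other extracellular matrix, the myofibroblast and TGF-beta response, lining-layer and sublining fibroblast markers, the ETS transcription factor family without Ets1, AP-1 and immediate-early genes, the heat shock response, the cell cycle, WNT, BMP and hedgehog ligands and antagonists, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, and glycolysis with the hypoxia response. A further 17 lists hold markers of other cells (macrophages and monocytes, neutrophils, T and NK cells, B and plasma cells, mast cells, endothelial cells, mural cells, skeletal muscle, chondrocytes, osteoblasts and osteocytes, osteoclasts, tenocytes, adipocytes, Schwann and nerve cells, keratinocytes, erythroid cells and platelets) and sex-linked genes. Lists with 5 or more tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg within each of the 2 families. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes. The fry p given here asks whether the list's genes move, on balance, one way, and does not compare them with other genes.

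The pipeline was tested on simulated data, in 5 simulations with 200 changed genes each at the depth and spread of these libraries. The edgeR test found 14% of genes changed 1.5-fold, 65.7% of genes changed 2-fold and 93.3% of genes changed 4-fold, and called 0.0889% of unchanged genes. DESeq2 found 16.1%, 66.6% and 95.2% and called 0.151% of unchanged genes, and voom found 12.2%, 62.1% and 92.7%. As counts, DESeq2 called 85 unchanged genes beside 54, 223 and 314 genes changed 1.5-fold, 2-fold and 4-fold. The same counts were 50 beside 47, 220 and 308 for edgeR, and 45 beside 41, 208 and 306 for voom. False calls were thus a larger share of the calls than the threshold of 0.05 for each tool, and the largest for DESeq2. Camera found a planted list of 20 genes changed 1.5-fold in 5 of 5 simulations and called 0 of 100 unchanged lists. The simulated genes varied independently of each other, with the gene-wise dispersions of the edgeR fit and no differences between whole libraries. The shares of genes found and of false calls may therefore not hold in the real data. For the same reason the 0 of 100 does not cover lists whose members vary together. In the real data the estimated correlation of the chondrocyte list was 0.763.

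Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals only), no filter and a stricter filter (5 CPM in at least 3 libraries), the other tests, an adjusted p of 0.1, a prior count of 0.5, and leaving out each library in turn. Chosen after seeing the data were edgeR without robust estimation, leaving out Ets1-flox replicates 4 and 5 together, counts thinned to equal totals, and DESeq2 without single libraries. The sequence of the pseudogene Gm7334 was compared with annotated transcripts by blastn 2.17.0, and overlaps of genes were found with bedtools 2.31.1.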

Results

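The data are read counts per gene from 6 libraries of sorted synovial fibroblasts, 3 from Ets1-flox mice (replicates 2, 4 and 5) and 3 from Ets1-ΔFib mice (replicates 1, 3 and 6), all with serum-induced arthritis. Total counts were 4922038, 6141604 and 5973516 in the Ets1-flox libraries, in that order, and 4812047, 4824289 and 5081455 in the Ets1-ΔFib libraries. Between 14781 and 15748 genes had a count in each library. Transcripts of matrix and lining-layer genes were among the most abundant, with means over the 6 libraries of 66672 CPM for Col3a1, 39782 CPM for Col1a1, 29956 CPM for Prg4 (lubricin, a joint lubricant) and 28071 CPM for Fn1 (fibronectin). Lars2, a gene of mitochondrial translation, had 30485 CPM, against 2921.6 CPM for mt-Co1. Whether all reads counted for Lars2 come from its transcript was not tested.

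Of the genes of the sort markers, Pdpn had 190 ± 17.0 CPM in Ets1-ΔFib and 168 ± 21.8 CPM in Ets1-flox (SD, n = 3 each). Ptprc, the gene of CD45, had 9 counts in Ets1-flox replicate 4 and 0 in the other 5 libraries, where a count of 0 allows up to 0.502 to 0.623 CPM. Mcam, the gene of CD146, had 6 to 14 counts per library, below the filter for testing. Pecam1, the gene of CD31, had 54 and 66 counts in Ets1-flox replicates 4 and 5, 29 in Ets1-ΔFib replicate 1 and 3 to 7 in the other 3 libraries. Its log2 change was -1.51, and ranged from -3.26 (without Ets1-ΔFib replicate 1) to -1.02 over single libraries left out.

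Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.961 to 0.968 between libraries of a group and 0.952 to 0.97 between groups. The first principal component held 40% of the variance of the 500 most variable genes, with Ets1-flox replicate 5 at -22.6 and Ets1-ΔFib replicate 3 at 21.7 as its ends. The labels give no sequencing batch.

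The comparison of Ets1-ΔFib with Ets1-flox asks how fibroblasts of the inflamed joint express their genes in mice where Col6a1-Cre deletes floxed Ets1 in cells that express the Cre. Ets1 is a transcription factor of the ETS family. The share of sorted cells with the deletion is not given in the sources used here. Ets1 itself (ENSMUSG00000032035, chromosome 9, 32636221 to 32757820) was lower in each Ets1-ΔFib library than in any Ets1-flox library. It had 35.8 ± 1.54 CPM in Ets1-ΔFib and 51.4 ± 6.92 CPM in Ets1-flox (SD, n = 3 each). The counts were 171, 165 and 187 against 217, 381 and 294. The log2 change was -0.52 (SE 0.137, 95% interval -0.82 to -0.22), which is -30.3%. Whether the remaining counts come from exons that are not floxed or from cells without the deletion was not tested. The edgeR test gave an unadjusted p of 0.00234 for Ets1, which was fixed in advance as a check of the labels. Its adjusted p was 0.506 with Benjamini-Hochberg over all genes. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. Col6a1, whose regulatory sequence drives the Cre, had 2956 ± 290 CPM in Ets1-ΔFib and 2985 ± 496 CPM in Ets1-flox.

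**Figure D1:**
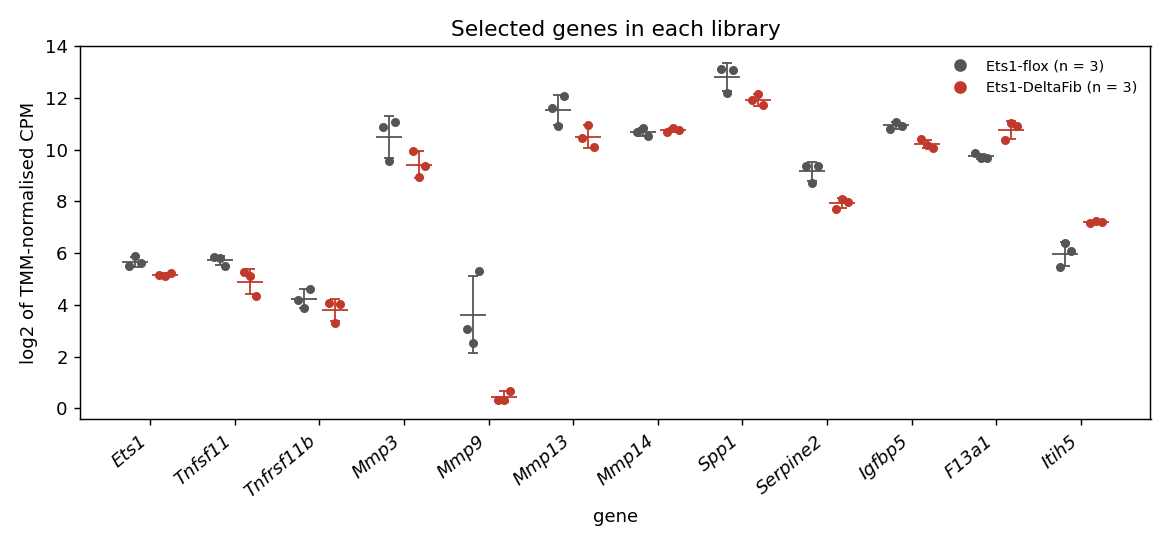
Log2 CPM (TMM-scaled) of selected genes in each library, with points for the 3 Ets1-flox and the 3 Ets1-ΔFib libraries and bars for the mean ± SD. Ets1, Tnfsf11 and Serpine2 are lower in each Ets1-ΔFib library than in any Ets1-flox library, with log2 changes of -0.52, -0.78 and -1.25, and F13a1 is higher, with 1.05.

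Serpine2, a secreted inhibitor of serine proteases, and F13a1, the enzyme subunit of the transglutaminase coagulation factor XIII, had the smallest p among the genes that the naming rule admits. Serpine2 had 246 ± 33.9 CPM in Ets1-ΔFib and 587 ± 141 CPM in Ets1-flox (log2 change -1.25, SE 0.181, n = 3 each). F13a1 had 1784 ± 412 CPM against 859 ± 65.4 CPM (log2 change 1.05, SE 0.165). Of the 20 genes with the lowest p among those that the naming rule admits, 13 were lower and 7 were higher in Ets1-ΔFib. None of the 20 overlapped between the groups, which a choice by low p favours.

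Secreted and matrix-related products among the lower ones were Col23a1 (a transmembrane collagen) at -1.80 on the log2 scale, Igfbp5 (a binding protein of insulin-like growth factors) at -0.73, Crispld2 at -0.70, Lrg1 (a secreted leucine-rich glycoprotein) at -2.27, Penk (the enkephalin precursor) at -1.39 and Slit2 (a secreted guidance cue) at -1.65. Membrane-associated products were Fxyd5 (a regulator of the sodium pump) at -0.68, Adcy4 (an adenylyl cyclase) at -1.68, Naalad2 at -1.28, Pear1 at -1.81, Tspan7 at -2.12 and Plekhb2 at -0.76. The higher ones were Pla1a (a phospholipase) at 1.04, Atp6v0d2 (a subunit of the vacuolar proton pump) at 2.17, Rcan2 (a regulator of calcineurin) at 0.82, Mmp23 at 0.55, Itih5 (a heavy chain of the hyaluronan-binding inter-alpha-trypsin inhibitors) at 1.19 and Vegfd (a lymphatic growth factor) at 0.77. Itih5 had 148 ± 3.96 CPM against 65.0 ± 20.4 CPM. Over single libraries left out, Lrg1 ranged from -2.89 (without Ets1-ΔFib replicate 1) to -1.83 and Tspan7 from -2.71 (without Ets1-ΔFib replicate 3) to -1.88. Pear1 had 20.4 and 19.1 CPM in Ets1-flox replicates 4 and 5, which had the highest endothelial marker sums, and 9.20 CPM in Ets1-flox replicate 2. Lrg1 had 22.4, 18.6 and 19.0 CPM in the same libraries. Whether cells other than fibroblasts contributed to the values of these 20 genes was not tested.

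With edgeR, 0 of 11473 genes passed an adjusted p of 0.05, and 0 passed 0.1. The smallest adjusted p was 0.124, shared by 3 genes, and 570 genes had an unadjusted p below 0.05, of which 269 were higher and 301 lower in Ets1-ΔFib. DESeq2 called 36 genes, 11 higher and 25 lower, and 35 of these did not overlap between the groups. In the simulations false calls were a larger share of the DESeq2 calls than 0.05, so single DESeq2 calls named below carry this limit. The DESeq2 count was 65, 18, 23 and 12 without Ets1-ΔFib replicate 1, Ets1-ΔFib replicate 3, Ets1-flox replicate 5 and Ets1-ΔFib replicate 6. Limma voom called 2, Gh and Gm7334, both without a count in Ets1-flox, and voom with quality weights also called 2. Over all tested genes, 1153 did not overlap between the groups (588 higher, 565 lower), which is 10.05% against the 10% that chance gives for 3 against 3. Leaving out Ets1-ΔFib replicate 1, Ets1-flox replicate 2 or Ets1-flox replicate 4 gave 8, 5 and 7 edgeR calls, leaving out Ets1-ΔFib replicate 3 or Ets1-flox replicate 5 gave 1 each, and leaving out Ets1-ΔFib replicate 6 gave 0. Without a filter on low counts edgeR called 121 of 19531 genes.

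Of the fixed genes of bone resorption and matrix breakdown (Tnfsf11, Tnfrsf11b, Mmp3, Mmp9, Mmp13 and Mmp14), edgeR called none and DESeq2 called Mmp9. In the fixed lists of matrix, proteases and osteoclast markers DESeq2 also called Spp1 and Serpine2, both lower, and Atp6v0d2, which was higher (DESeq2 adjusted p 0.00166). Spp1 (osteopontin) had 3940 ± 614 CPM in Ets1-ΔFib and 7517 ± 2430 CPM in Ets1-flox (SD, n = 3 each), with a DESeq2 adjusted p of 0.00351. Mmp9 (gelatinase B) had 1.37 ± 0.208 CPM against 17.8 ± 18.7 CPM, with 39.4 CPM in Ets1-flox replicate 5 and a DESeq2 adjusted p of 0.0241. Its log2 change was -3.68, and -2.33 without that library. Tnfsf11 (RANKL, the cytokine that drives osteoclast formation; chromosome 14, 78277445 to 78308043) had 31.0 ± 9.48 CPM against 53.3 ± 6.50 CPM, lower in each Ets1-ΔFib library, with an edgeR adjusted p of 0.585. Its decoy receptor Tnfrsf11b (osteoprotegerin) had 14.4 ± 3.86 CPM against 19.3 ± 4.98 CPM. Mmp3 (stromelysin) had 715 ± 262 CPM against 1589 ± 727 CPM, and Mmp13 (a collagenase) 1498 ± 465 CPM against 3155 ± 1199 CPM, and in both genes the groups overlapped. Mmp14 had 1736 ± 77.1 CPM against 1648 ± 163 CPM. Il6 had 21.0 ± 15.3 CPM against 27.2 ± 15.4 CPM, with overlap of the groups and a log2 change of -0.37. Over single libraries left out, the Il6 change ranged from -1.16 (without Ets1-ΔFib replicate 1) to -0.076.

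The osteoclastogenesis regulators fell as a list, with 17 of 22 tested members lower in Ets1-ΔFib, a median log2 change of -0.31 and a camera adjusted p of 0.0133. Members have opposite roles, such as Tnfsf11 and its decoy receptor Tnfrsf11b (log2 change -0.43), so the fall gives no direction for osteoclast formation. Wnt5a, Sfrp1 and Dkk1 are also in the list of WNT, BMP and hedgehog ligands and antagonists. The list had an adjusted p = 0.912 with an estimated correlation and 0.955 by fry. Adjusted over all genes 0 of its members passed, and adjusted over the list alone 2 were lower, Tnfsf11 (log2 change -0.78) and Il11 (-1.60), a cytokine of the gp130 family. The call was lost without Ets1-ΔFib replicate 3 (0.483) or Ets1-flox replicate 5 (0.0576). This list is 1 of 4 gene lists that passed camera with the preset correlation. Of the 10 splits of the 6 libraries into 3 and 3, examined afterwards, 9 gave at least 4 gene lists, the real split included. Cartilage markers (median log2 change -2.37) and endothelial markers (-1.51) were also lower in Ets1-ΔFib, with the highest cartilage sum in Ets1-flox replicate 5.

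The matrix metalloproteinases split. Of 13 tested members, 7 were higher and 6 lower, and the median change was 0.07 while the mean was -0.39. Camera pointed down with an adjusted p of 0.96 and fry pointed up. Adjusted over the list alone 1 was higher, Mmp23 (114 ± 8.39 CPM against 77.8 ± 1.79 CPM). Mmp12 (macrophage elastase) was at -1.60 on the log2 scale, and at -0.94 without Ets1-flox replicate 2, which had 48 counts against 17 and 27 in Ets1-flox replicates 4 and 5. Among other matrix proteases and inhibitors, 20 of 35 members were higher (median 0.02, mean -0.04, camera up with adjusted p 0.96, fry down), and adjusted over the list alone 1 was lower, Serpine2. Fap (a fibroblast surface protease) was at -0.38.

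The WNT, BMP and hedgehog ligands and antagonists fell as a list, with 20 of 28 tested members lower, a median log2 change of -0.41 and a camera adjusted p of 0.0133. It had an adjusted p = 0.912 with an estimated correlation and 0.955 by fry. Adjusted over the list alone 1 was higher, Rspo2 (an enhancer of WNT signalling; 74.6 ± 19.2 CPM against 44.7 ± 8.43 CPM), and 2 were lower, Inhba (the activin A subunit; 128 ± 22.1 CPM against 190 ± 27.3 CPM) and Bmp2 (-0.76). The call was lost without Ets1-ΔFib replicate 3 (0.494), without Ets1-flox replicate 5 (0.102), without a filter (0.153) and with the stricter filter (0.119). Ets1-flox replicate 5, with the highest cartilage marker sum, also had the highest count of Wif1, a secreted WNT antagonist (538 against 24 to 72 in the other 5 libraries).

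The heat shock response fell as a list, with 14 of 15 members lower, a median of -0.20 and a camera adjusted p of 0.00133. This list had an adjusted p = 0.912 with an estimated correlation and 0.955 by fry. Hspa1a, an inducible chaperone, had 502 ± 102 CPM in Ets1-ΔFib and 978 ± 336 CPM in Ets1-flox and was called by DESeq2 (adjusted p 0.00267), and Hsp90aa1 was at -0.34. The mitochondrially encoded genes, which make subunits of the respiratory chain, fell as a list, with 12 of 13 lower, a median of -0.24 and a camera adjusted p of 0.000258. The mitochondrial list also had an adjusted p = 0.912 with an estimated correlation and 0.955 by fry. Examples are mt-Nd4 at -0.30 and mt-Atp8 at -0.33. In both lists 0 members passed adjusted over the list alone. The heat shock call was lost without Ets1-ΔFib replicate 3 (0.121) or Ets1-flox replicate 4 (0.0673), and the mitochondrial call without Ets1-flox replicate 5 (0.0539). Ets1-flox replicates 4 and 5 also had the highest sums of endothelial markers, 188 CPM each, and the lowest shares of Lars2 counts. These shares were 1.82% (95% Wilson interval 1.81% to 1.83%) and 2.155% (2.14% to 2.17%), against 3.29% (3.27% to 3.31%) in Ets1-ΔFib replicate 1, 3.76% (3.74% to 3.78%) in Ets1-flox replicate 2, 3.46% (3.45% to 3.48%) in Ets1-ΔFib replicate 3 and 3.81% (3.79% to 3.83%) in Ets1-ΔFib replicate 6.

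The remaining 15 gene lists did not pass camera. None had an adjusted p below 0.912 with an estimated correlation, and fry gave 0.955 for each. Among inflammatory cytokines and chemokines 16 of 30 members were lower (median -0.10, camera adjusted p 0.309), with Ccl20 at -1.37. Among NF-kB targets 14 of 21 were lower (-0.14, 0.309), with Traf1 at -0.99 and Tnfaip2 at 0.30. In gp130-STAT3 signalling 15 of 24 were lower (-0.10, 0.413), with the acute-phase gene Hp called by DESeq2 at 1104 ± 244 CPM against 1887 ± 505 CPM (adjusted p 0.0241). Among interferon-stimulated genes 17 of 28 were higher (0.07, 0.96), with Irf7 at 0.40 and Psmb8 at -0.24. Leaving out Ets1-ΔFib replicate 1 gave the inflammatory list an adjusted p of 0.000206, leaving out Ets1-flox replicate 2 gave the NF-kB targets 0.0193, and leaving out Ets1-ΔFib replicate 3 gave the interferon list 0.0197.

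Matrix genes went both ways. Of the fibrillar collagens and collagen assembly genes 19 of 35 were higher (median 0.01, mean -0.17, camera down, adjusted p 0.96), with Loxl3 at -0.29 and Col16a1 at -0.36. Of the other extracellular matrix genes 20 of 40 were lower (-0.03, adjusted p 0.982), among them Spp1 and Cilp2 (-0.92). In the myofibroblast and TGF-beta response 17 of 28 were higher (0.12, 0.537), with the receptor gene Tgfbr1 at 0.43. Of the lining-layer markers 16 of 22 were higher (0.19, 0.225), with Col22a1 at 0.56, and of the sublining markers 16 of 29 were lower (-0.03, 0.557), with Mfap5 at 0.32. In these lists 0 members passed adjusted over the list alone except 1 lower sublining marker, Penk (11.2 CPM against 29.3 CPM, log2 change -1.39, SE 0.281). Without Ets1-ΔFib replicate 1, the lining markers had an adjusted p of 0.0199 (higher) and the sublining markers 0.00516 (lower).

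For regulators and housekeeping lists, 8 of 15 other ETS family genes were lower (median -0.03, mean 0.02, camera up, adjusted p 0.873), with Elf1 at 0.22 and Elf4 at 0.23. Of the AP-1 and immediate-early genes 18 of 27 were lower (-0.08, 0.8), with Nr4a2 at -0.42 and Dusp2 at -1.37. Over single libraries left out, Dusp2 ranged from -2.12 (without Ets1-ΔFib replicate 1) to -1.02. Of the cell cycle genes 22 of 40 were lower (-0.01, 0.96), with Cdc20 at 0.45 and Rrm1 at 0.27. Of the cytosolic ribosomal protein genes 48 of 63 were lower (-0.04, 0.309), with Rpl8 at -0.26 and Rpl22 at -0.20. Of the nuclear oxidative phosphorylation genes 25 of 42 were lower (-0.01, 0.96), with Ndufa4 at 0.27 and Ndufb10 at -0.30, and of the glycolysis and hypoxia genes 19 of 24 (-0.06, 0.322), with Pfkfb3 at -0.63 and Slc2a1 at -0.39. In these lists, and in the inflammatory, NF-kB, gp130 and interferon lists, 0 members passed adjusted over the list alone. The AP-1 list had an adjusted p of 0.0193 without Ets1-flox replicate 2, the cell cycle list 0.0128 without Ets1-flox replicate 5, and the ribosomal list 0.00172 without Ets1-ΔFib replicate 1 and 0.0347 without Ets1-flox replicate 4.

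Cartilage markers were lower in Ets1-ΔFib, with 13 of 13 tested members of the chondrocyte list below Ets1-flox, a median log2 change of -2.37 and a camera adjusted p of 4.85e-09. The chondrocyte list had an adjusted p = 0.482 with an estimated correlation and 0.576 by fry. Adjusted over the list alone 2 were lower, Sox9, the transcription factor of cartilage formation (87.5 ± 17.9 CPM against 138 ± 31.2 CPM), and Chad, a cartilage matrix protein (17.7 ± 1.88 CPM against 70.3 ± 42.8 CPM, a log2 change of -1.99 that was -1.36 without Ets1-flox replicate 5). Col2a1, the main cartilage collagen, had 30175 counts in Ets1-flox replicate 5 and 266 to 2104 in the other 5 libraries. The list summed to 1204, 720 and 8065 CPM of library totals in Ets1-flox replicates 2, 4 and 5 and to 702, 376 and 677 CPM in Ets1-ΔFib replicates 1, 3 and 6. Without Ets1-flox replicate 5 the median was -1.05, with a camera adjusted p of 1.78e-08 and an adjusted p = 0.419 with an estimated correlation.

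Endothelial markers were lower as a list, with 8 of 9 members lower, a median of -1.51 and a camera adjusted p of 7.49e-05. The endothelial list had an adjusted p = 0.482 with an estimated correlation and 0.576 by fry. Its members summed to 72.3, 188 and 188 CPM in Ets1-flox replicates 2, 4 and 5 and to 93.5, 53.3 and 58.3 CPM in Ets1-ΔFib replicates 1, 3 and 6. Adjusted over the list alone 1 was lower, Eng (endoglin; 35.6 ± 3.09 CPM against 52.4 ± 10.7 CPM), and DESeq2 called Egfl7 (adjusted p 0.0215). Markers of osteoblasts and osteocytes were lower as a list, with 7 of 9 lower, a median of -0.95 and a camera adjusted p of 0.0288. The bone list had an adjusted p = 0.735 with an estimated correlation and 0.665 by fry. Adjusted over the list alone 1 was lower, Phex (1.38 ± 0.628 CPM against 5.85 ± 4.60 CPM), a peptidase of phosphate handling, and Bglap (osteocalcin) was at -2.38. Phex went from -2.08 to -1.20 and Bglap to -1.70 on the log2 scale without Ets1-flox replicate 5, and Bglap to -3.27 without Ets1-ΔFib replicate 3. With Ets1-flox replicates 4 and 5 left out together, a choice made after seeing the data, the endothelial median was 0.90 (adjusted p 0.95). The bone call was lost without Ets1-ΔFib replicate 1 (0.368), Ets1-ΔFib replicate 6 (0.0556) or Ets1-flox replicate 5 (0.824, with a median of -0.05 and 5 of 9 members lower). It was also lost without a filter (0.0884) and with the stricter filter (0.293).

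**Figure D2:**
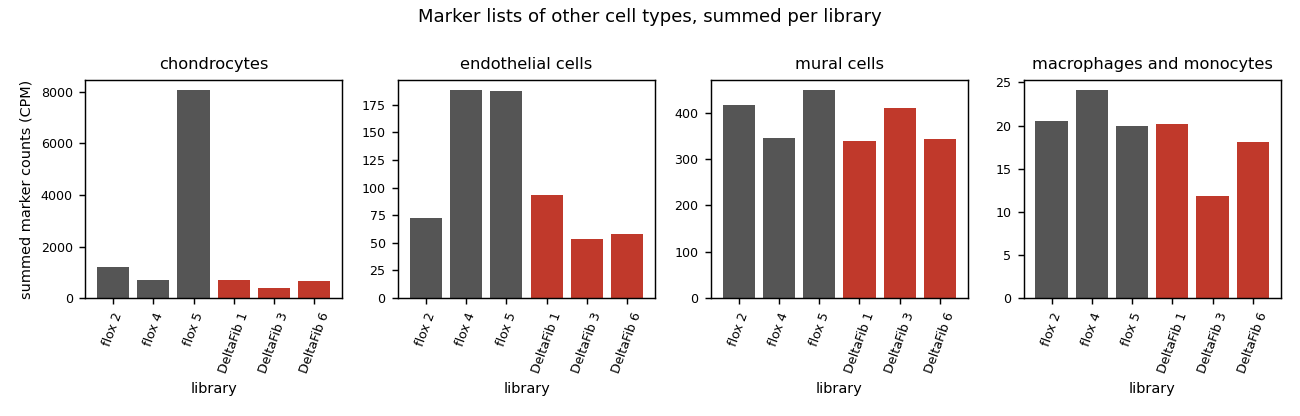
Bars give the summed counts of 4 marker lists of other cells in each library, as CPM of library totals on linear axes that start at 0 and differ between panels, for the 3 Ets1-flox and the 3 Ets1-ΔFib libraries. Cartilage markers reach 8065 CPM in Ets1-flox replicate 5, and endothelial markers reach 188 CPM in Ets1-flox replicates 4 and 5 against 53.3 to 93.5 CPM in the other 4 libraries.

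Markers used by osteoclasts did not shift as a list (4 of 6 lower, median -0.10, mean -0.24, camera up with adjusted p 0.694). Adjusted over the list alone 2 were higher, Atp6v0d2 (10.2 ± 4.87 CPM against 2.22 ± 0.556 CPM) and Acp5, the gene of tartrate-resistant acid phosphatase (157 ± 4.32 CPM against 117 ± 8.76 CPM), and 1 was lower, Mmp9. The tenocyte list (4 of 7 higher, median 0.13, adjusted p 0.694) held Comp at -0.58 and Kera at 0.85, and the mural cell list (5 of 7 lower, -0.09, 0.84) held Notch3 at 0.51 and Acta2 at -0.34. Lists with fewer than 5 tested members were not tested with camera. Of the Schwann and nerve cell markers, adjusted over the list alone 1 of 4 was lower, S100b at -1.08 (median 0.02, mean -0.19), with Pmp22 at 0.08. The other lists of this kind had 0 past, adjusted over the list alone. They held Cd14 (-0.39) and Lyz2 (-0.29) among 3 macrophage markers, Lcn2 (-0.83, and -0.092 without Ets1-flox replicate 5) for neutrophils, Fabp4 (-0.27) for adipocytes, Krt10 (0.14) for keratinocytes, Hbb-bs (0.68, and -2.73 without Ets1-ΔFib replicate 6 or 1.74 without Ets1-flox replicate 5) and Itga2b (0.24) for erythroid cells and platelets, and Ddx3y (-0.30) and Eif2s3y (0.11) among 4 sex-linked genes (median 0.02, mean -0.04). Markers of T and NK cells, B and plasma cells, mast cells and skeletal muscle had 0 genes above the filter, and summed to 3 to 33, 1 to 8, 0 to 12 and 9 to 34 counts per library.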

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

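The settings that left out Ets1-flox replicates 4 and 5 together, thinned the counts, left out robust estimation, or left libraries out of DESeq2 were chosen after seeing the data. All others were planned. The Ets1 change kept its direction in all settings, from -0.60 (without Ets1-flox replicate 2) to -0.34 (without Ets1-flox replicates 4 and 5). Its p adjusted over all genes passed 0.05 in none. Of 1469 values of the 87 named genes over the settings, 1383 kept direction and side of the threshold, 72 passed it newly (34 without a filter, 23 by DESeq2) and 14 turned sign, over 10 genes. Of the 7 called lists, only the chondrocyte list kept its call in every setting except an estimated correlation and fry. Depth limits genes near 3 counts, 0.488 to 0.623 CPM per library. Where no cause is given, the cause was not tested.

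The edgeR count of 0 became 1 with library totals only (Serpine2), 121 without a filter, 36 by DESeq2, 2 by voom, 2 by voom with weights and 4 without Ets1-flox replicates 4 and 5, and ranged from 0 (without Ets1-ΔFib replicate 6) to 8 (without Ets1-ΔFib replicate 1) over single libraries left out. Without a filter 97 of the 121 genes had also been tested with it, the prior degrees of freedom went from 8.51 to infinite, and 1136 genes had an unadjusted p below 0.05, against 570. The DESeq2 count of 36 became 14 without Ets1-flox replicates 4 and 5 and ranged from 12 (without Ets1-ΔFib replicate 6, 10 of the 36 kept) to 65 (without Ets1-ΔFib replicate 1, 20 kept), with 18 without Ets1-ΔFib replicate 3 and 23 without Ets1-flox replicate 5.

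The 4 gene lists past camera became 0 with an estimated correlation and 0 by fry, and ranged from 2 (without Ets1-ΔFib replicate 3 or Ets1-flox replicate 5) to 8 (without Ets1-ΔFib replicate 1). The 3 other-cell lists became 0 with an estimated correlation, 0 by fry and 1 with the strict filter. With the strict filter the endothelial list had too few members left to be tested. With an estimated correlation the adjusted p of the lists of osteoclastogenesis regulators, heat shock response, WNT, BMP and hedgehog ligands and antagonists, and mitochondrially encoded genes was 0.912 each, that of endothelial cells and chondrocytes 0.482 each, and that of osteoblasts and osteocytes 0.735. By fry the values were 0.955 for each of the 4 gene lists, 0.576 for endothelial cells and chondrocytes and 0.665 for osteoblasts and osteocytes. The WNT, BMP and hedgehog list had 0.153 without a filter and 0.119 with the strict filter, and osteoblasts and osteocytes had 0.0884 and 0.293.

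Without Ets1-flox replicates 4 and 5, which leaves 1 Ets1-flox library assumed to vary like the others, the adjusted p were 0.188 for osteoclastogenesis regulators, 0.592 for heat shock response, 0.143 for the WNT, BMP and hedgehog list, 0.143 for mitochondrially encoded genes and 0.95 for osteoblasts and osteocytes. The direction turned there for endothelial cells (0.95), other matrix proteases and inhibitors (0.592), NF-kB targets (0.27), gp130-STAT3 signalling (0.804), interferon-stimulated genes (0.734), the myofibroblast and TGF-beta response (0.547), the ETS family (0.734), AP-1 and immediate-early genes (0.00937, higher), glycolysis and hypoxia (0.958), osteoclasts (0.95) and tenocytes (0.898). Cytosolic ribosomal proteins (2.13e-05), cell cycle (0.000776) and nuclear oxidative phosphorylation (0.0402) passed there, all lower. All passes in this setting used the preset correlation, and that of the AP-1 list was lost with an estimated correlation and by fry. Among named genes, the direction turned in this setting for Pecam1 (0.74), Dusp2 (0.047), Pfkfb3 (0.17) and Slc2a1 (0.082).

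The direction turned for other extracellular matrix with upper-quartile scaling (0.966). Without a filter it turned for fibrillar collagens and collagen assembly, other extracellular matrix, cell cycle and nuclear oxidative phosphorylation (0.897 each) and osteoclasts (0.985). By fry it turned for matrix metalloproteinases and other matrix proteases and inhibitors (0.955 each), and in thinned counts for cell cycle (0.968). By voom Hbb-bs turned (-0.040), and by voom with weights Col6a1 (0.0067).

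Over single libraries left out, log2 changes that turned ranged from -0.15 (without Ets1-flox replicate 4) to 0.064 (without Ets1-flox replicate 5) for Col6a1, -0.77 to 0.10 (without Ets1-ΔFib replicates 6 and 3) for Lyz2, -0.58 to 0.068 (without Ets1-ΔFib replicate 3 and Ets1-flox replicate 2) for Acta2, -0.044 to 0.23 (without Ets1-ΔFib replicates 6 and 3) for Pmp22, -2.73 to 1.74 (without Ets1-ΔFib replicate 6 and Ets1-flox replicate 5) for Hbb-bs, and -0.0022 to 0.25 (without Ets1-ΔFib replicates 1 and 6) for Eif2s3y.

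The lowest and highest adjusted p of called lists over single libraries left out were 0.000236 and 0.483 (without Ets1-ΔFib replicates 1 and 3) for osteoclastogenesis regulators, 5.35e-05 and 0.121 (without Ets1-flox replicate 2 and Ets1-ΔFib replicate 3) for heat shock response, 4.45e-05 and 0.494 (without Ets1-ΔFib replicates 1 and 3) for the WNT, BMP and hedgehog list, 8.75e-05 and 0.0539 (without Ets1-ΔFib replicate 6 and Ets1-flox replicate 5) for mitochondrially encoded genes, and 0.000963 and 0.824 (without Ets1-flox replicates 2 and 5) for osteoblasts and osteocytes. Chondrocytes and endothelial cells kept their calls, at 3.42e-13 to 1.07e-05 and 2.12e-12 to 0.00872.

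Of the 20 tested lists that were not called, 8 passed without some single library. Their lowest and highest values were 0.000206 and 0.571 (without Ets1-ΔFib replicates 1 and 3) for inflammatory cytokines and chemokines, 0.0193 and 0.821 (without Ets1-flox replicate 2 and Ets1-ΔFib replicate 6) for NF-kB targets, 0.0197 and 0.932 (without Ets1-ΔFib replicate 3 and Ets1-flox replicate 5) for interferon-stimulated genes, 0.00516 and 0.52 (without Ets1-ΔFib replicate 1 and Ets1-flox replicate 5) for sublining markers, 0.0193 and 0.881 (without Ets1-flox replicate 2 and Ets1-ΔFib replicate 6) for AP-1 and immediate-early genes, 0.0128 and 0.881 (without Ets1-flox replicate 5 and Ets1-ΔFib replicate 6) for cell cycle, and 0.00172 and 0.494 (without Ets1-ΔFib replicates 1 and 3) for cytosolic ribosomal proteins, and each of these 7 turned direction for some single library. Lining markers had 0.0199 without Ets1-ΔFib replicate 1. Other lists that turned for some single library ranged from 0.567 to 0.975 for matrix metalloproteinases, 0.533 to 0.975 for other matrix proteases and inhibitors, 0.131 to 0.963 for fibrillar collagens and collagen assembly, 0.194 to 0.973 for other extracellular matrix, 0.115 to 0.978 for the myofibroblast and TGF-beta response, 0.18 to 0.963 for nuclear oxidative phosphorylation, 0.323 to 0.915 for mural cells and 0.224 to 0.915 for tenocytes.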

Other observations

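All technical explanations weighed here, and the counts over other splits of the samples, were tested only after the results were seen. Outside the naming rule, DESeq2 called further genes, some of which are described here, chosen after their values were seen. Prom1 (prominin, a membrane glycoprotein) had 3.99 ± 0.561 CPM in Ets1-ΔFib and 0.641 ± 0.0311 CPM in Ets1-flox (SD, n = 3 each; DESeq2 adjusted p 0.0389). Pamr1 had 201 ± 47.8 CPM against 117 ± 26.0 CPM, and Stac2 37.8 ± 13.6 CPM against 17.0 ± 4.85 CPM. Lower in Ets1-ΔFib were Fgfr2, a fibroblast growth factor receptor (16.1 ± 5.65 CPM against 39.0 ± 19.1 CPM), Podnl1 (8.42 ± 0.760 CPM against 19.9 ± 6.61 CPM) and Col10a1, the collagen of hypertrophic cartilage (0.973 ± 0.857 CPM against 5.84 ± 2.45 CPM). Their DESeq2 adjusted p were 0.0241, 0.0168, 0.0234, 0.0288 and 0.0271 in the order from Pamr1 on, and edgeR called none of them.

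Some genes had counts in 1 group alone, with at least 3 counts in each of its libraries: 3 in Ets1-ΔFib and 4 in Ets1-flox. Cd244a, an immune receptor gene, had 4, 6 and 13 counts in Ets1-flox replicates 2, 4 and 5 and 0 in Ets1-ΔFib, 6.62-fold above a floor of 3 counts over the group. Such folds take the summed counts as measured, without their own error, so they are not lower limits. The genes were picked for this pattern, and other splits of the libraries were not searched for it. Besides Gh and Gm7334, the others were D630024D03Rik in Ets1-ΔFib (3.86-fold above the floor) and 5830432E09Rik (3.46-fold), 4930486L24Rik (3.74-fold) and Gm26533 (5.47-fold) in Ets1-flox.

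Gh, the growth hormone gene (chromosome 11, 106300271 to 106301865), had 10, 13 and 29 counts in Ets1-ΔFib, 20.1-fold above the same floor in Ets1-flox, which had 0. Gm7334 (chromosome 17, 50698688 to 50699443), a processed pseudogene, had 11, 30 and 36 counts, 29.7-fold above it. The tables argue against RNA of pituitary cells as the source of Gh, since Prl had 1 count beside 52 of Gh, and Pomc had 5 counts in each group. Reads shared at one rate between Gm7334 and Btg3, which are identical over 756 of 756 bases, are argued against too, since the ratio of Gm7334 to Btg3 in the Ets1-ΔFib libraries gives 102 Gm7334 counts in Ets1-flox, where Btg3 had 1260 counts and Gm7334, singled out for this, had 0. A segment of another strain around Gm7334 may be a source and stays open. Within 10 Mb, 3 of 113 tested genes had an unadjusted p below 0.01, namely Rcan2, Enpp5 and Lrg1 (2.65% against 1.42% elsewhere, Fisher's exact p 0.219). Rcan2 and Lrg1 are among the 20 genes with the lowest p described above. Such a segment stays open around Gh too, where 7 of 229 tested genes had such a p, Sox9 and Stac2 among them (3.06% against 1.4%, Fisher's exact p 0.0462, adjusted over 4 windows 0.185). Sequence carried by the Cre transgene is another candidate source that stays open for both Gh and Gm7334, as does an effect of the Ets1 deletion: 3 of 3 Ets1-ΔFib libraries held 10 or more Gh counts, which each would give, and the sources used here do not describe the transgene.

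Cartilage markers were lower in Ets1-ΔFib, and cartilage cells in the library of Ets1-flox replicate 5 could be a source of the difference. Without that library the median log2 change was -1.05 with an upper quartile of -0.45 and 13 of 13 members lower (camera adjusted p 1.78e-08, range 3.42e-13 to 1.07e-05 over all libraries left out in turn), but the list had an adjusted p = 0.419 with an estimated correlation and 0.472 by fry (0.482 and 0.576 with all libraries), so whether it is the whole cause stays open, although Chad was then the 1 gene that edgeR called (log2 change -1.36, 43.7 and 47.5 CPM in Ets1-flox replicates 2 and 4 against 16.6 to 19.9 CPM in Ets1-ΔFib). In counts thinned to equal totals the median was -2.60, with an upper quartile of -1.63 and 12 of 12 tested members lower. These values argue against unequal library totals as the cause. What made the totals differ was not tested. A smaller share of cartilage cells in all Ets1-ΔFib libraries, of which the PDPN-positive gate should remove those without PDPN, and a lower expression by fibroblasts of Ets1-ΔFib mice both stay open, untested. Of the 14 listed genes, 13 passed the filter in these libraries, and other lists also hold Acan, Col2a1 and Col11a1.

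Osteoclastogenesis regulators were lower in Ets1-ΔFib, with a median of -0.31, and other cells in the libraries of Ets1-flox replicates 4 and 5 may contribute, where endothelial markers, of a cell type that the CD31-negative gate should remove, summed to 188 CPM each. Without both libraries the median was -0.111 (quartiles -0.48 and 0.15, camera adjusted p 0.188), which leaves this open because 1 Ets1-flox library remains and members go both ways. Unequal library totals are argued against for this list as well. In counts thinned to equal totals its median was -0.31 (quartiles -0.393 and -0.115), with 17 of 22 tested members lower. Tnfsf11 was at -0.91 on the log2 scale without both libraries, against -0.78 with all. An effect of the Ets1 deletion stays open, untested.

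The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes by edgeR and the highest other gave 11 (10 of the 10 splits gave at least as many as the real one). At an unadjusted p below 0.05 the real split gave 570 genes and the highest other 741 (3 splits as many or more), and by DESeq2 it gave 36 and the highest other also 36 (2 splits). For lists past camera, the values were 4 and 11 for gene lists (9 splits) and 3 and 3 for other-cell lists (2 splits). The split of Ets1-ΔFib replicate 1 and Ets1-flox replicates 4 and 5 from the others gave the 11 edgeR genes, another split gave 4 and the other 7 gave 0. Whether the 11 reflect a structure of the samples beyond genotype was not tested. These 3 libraries had the 3 highest sums of endothelial markers (93.5, 188 and 188 CPM, against 53.3 to 72.3 CPM). The 741 genes came from another split (Ets1-ΔFib replicate 1 with Ets1-flox replicates 2 and 4).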
